A study of Homo sapiens with 4 samples.

How the data were processed

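The study hybridised RNA from HEK293 cells, a human embryonic kidney cell line, and from a HEK293 line stably expressing STAT6, each as an untreated control and after transfection with poly(I:C), a synthetic double-stranded RNA, for 16 h. Per the labels' protocols, total RNA with an integrity number of at least 7 was used, 2.5 µg of it was reverse-transcribed and amplified, and the amplified RNA was coupled to Cy5 or Cy3. Each line had 2 two-colour arrays that carried the same 2 RNA samples with the dyes exchanged, a technical dye swap, so the 4 arrays hold 4 RNA samples and 1 replicate per line. Nothing in the labels names a second culture for any condition. Each array had 39200 spots, of which 30968 were gene probes, 7156 were empty and 1076 were other controls.

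The deposited scanner tables give a linear spot intensity per channel, with the array and RNA sample of each column per the file headers; the scanner, its software and any summary of pixels are not given in the sources used here. No local background columns stand beside the intensities, and the empty spots had medians from 83 to 170, so no background had been subtracted. The tables also give a flag per spot, with the values 0, -50 and -75; 0 was read as found, and the empty spots carried -75. The order of the dyes was taken from the labels and checked on the Cy5 and Cy3 control spots, which were bright in the channel the labels name. The authors' value table holds log2 ratios, given for probes with the flag 0 on both arrays of a dye swap, with a normalization that is not given in the sources used here. Set against the intensities, its columns followed loess on intensities without background correction (r from 0.987 to 0.996 across probes, slopes from 0.973 to 0.991), with column medians of -0.01, 0.02, -0.01 and -0.02. All 4 columns run as poly(I:C) over control, whereas the labels describe the arrays with poly(I:C) in Cy3 as control over poly(I:C); the exact centring stays unknown.

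The intensities were processed with limma 3.58.1 in R 4.3.3. The plan had assumed foreground and local background columns; since there were only foreground intensities, the normexp correction with an offset of 50 was fitted on these alone. Log2 ratios were then normalized within each array by loess (span 0.3, 4 iterations) with control spots at weight 0, and each was turned to poly(I:C) over control. Control levels were compared across arrays as single-channel log2 levels after loess and Aquantile normalization, Cy5 against Cy5 and Cy3 against Cy3. The offset and the unsubtracted background pull the folds of dim probes toward 1. A probe at an intensity of 65535 was saturated, and a fold in which 1 RNA was saturated on both arrays is given as "at least". A channel above the 95th percentile of its empty spots was taken as above background. Later steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6.

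Gene names are those of the array: 17811 probes had 1 of 15597 names and 13157 had none. Of the names, 13130 were current symbols of the RefSeq annotation of GRCh38.p14, 2350 matched it through a single synonym and 117 did not match; 23 names had the form of a calendar date and are not printed. The annotation served for names alone, since no build is named for the probes, so no coordinates are given. A gene was represented by its brightest probe. Of 959 genes with more than 1 found probe in each line, the probes gave different calls for 2 genes in HEK293 and 10 in the HEK293-STAT6 line, never opposite ones.

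With 1 RNA sample per condition and line, the response of a line and the difference between lines leave no residual degrees of freedom, and no p-value is given; a test of poly(I:C) over both lines was not run. Genes were instead called by a rule of size: a mean log2 ratio over both arrays at least 1 from 0, each array at least 0.58 from 0 in that direction, and the flag 0 on both arrays. A response differed between the lines where the difference of the mean log2 ratios was at least 1 from 0 and both arrays of one line lay beyond both arrays of the other, for genes found in at least 1 line. Control levels followed the sizes of the first rule, with the comparison in each dye in place of the array, for genes found in at least 1 line. The 17 gene lists were described by the median over found members and its percentile among 10000 random lists matched on deciles of intensity. Named were 16 genes fixed in advance, the 10 largest rises and falls meeting the rule in each comparison, and per list up to 4 members meeting the rule, or the 2 largest values where none did; some of the list members this names are not reported here. All these rules, and the alternatives for background correction, normalization, source of the values, detection filter, dye, probes and threshold, were fixed before the data were examined. CCL2, CCL20 and CCL26 were put in their lists with knowledge of the study.

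The technical standard error of a mean log2 ratio was estimated from how far the dye terms (the difference between the orientations divided by 2) of the lines disagreed: 0.07 over all genes, and 0.12, 0.08 and 0.04 for the dimmest, middle and brightest of 3 equal groups. That of a difference between the lines was 0.11, and that of a control level difference 0.16. These cover hybridisation and scanning, not cultures, and the number of arrays limits the precision. The steps were tested on simulated arrays with known folds and the measured error. For HEK293 (9642 genes), 4.0% of genes changed 2-fold, 72.0% changed 3-fold and 94.0% changed 5-fold were called; for the HEK293-STAT6 line (9526 genes) 6.0%, 80.0% and 92.0%; for the difference (10091 genes) 8.0%, 78.0% and 90.0%; and for the control level (10091 genes) 12.0%, 72.0% and 90.0%. No unchanged gene was called in these 4 comparisons of one set of simulated arrays. The changed genes numbered 50 per fold, and 100 for the HEK293-STAT6 line. They were drawn from the 9077 genes found in both lines, with the measured flags kept. The percentages therefore do not cover genes found in only 1 line or losses through the flag. The simulated error was the technical one, far below the threshold, and both lines had the same dye term. The absence of false calls therefore says nothing of variation between cultures, or of a dye trend that differs between the lines. A true 3-fold change in HEK293 was estimated at a median of 2.46-fold.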

Results

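The response of HEK293 cells to transfected poly(I:C) was measured in the parental line and in a derivative stably expressing STAT6, a transcription factor best known from interleukin-4 signalling; the series' title names the activation of STAT6 by STING in antiviral immunity as its subject. Each line contributed 1 control RNA and 1 poly(I:C) RNA, hybridised together on 2 arrays with exchanged dyes. Of 15597 named genes, 9642 were found on both arrays of HEK293, 9526 on both arrays of the HEK293-STAT6 line, 9077 in both lines and 10091 in at least 1. Median intensities of the gene probes lay between 118 and 246 per channel, against 83 to 170 for empty spots, so most probes were dim. With 1 RNA sample per condition and line, every value below describes these samples and has no replicate check; the error given is the technical one of the dye swap.

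The first question was what poly(I:C) changed in the parental cells. Antiviral and inflammatory genes rose: OASL, a relative of the oligoadenylate synthetases, by a mean log2 ratio of 5.69 (51.8-fold), the chemokine CCL5 by 5.50 (45.3-fold), the ubiquitin-like modifier ISG15 by 4.12 (17.4-fold), and the interferon-induced IFIT1 and IFIT3 by 3.98 and 3.81. ISG20 rose by 3.01, CXCL10 by 2.73, IRF9, a subunit of the interferon-activated complex ISGF3, by 2.59, the RNA sensor IFIH1 by 2.22 and IFI6 by 2.14. A second CCL5 probe stood at 4.35. In all, 41 genes rose and 1 fell, the olfactory receptor gene OR51B4, at -1.29. The technical standard error of these means was 0.07 over all genes and 0.12 for dim ones. For comparison, 33 genes had the same sizes with opposite signs on the arrays. On single arrays, 91 genes (poly(I:C) in Cy5; 66 up, 25 down) and 216 genes (in Cy3; 60 up, 156 down) were at least 2-fold from equal, and the count depended on the threshold for the mean, with 73 genes at 1.5-fold and 22 at 3-fold.

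Of the interferon-stimulated genes, 16 of 41 found members rose and none fell, with a median log2 ratio of 0.70, above all 10000 random lists. NF-kappaB target genes had a median of 0.31, also above all random lists, and 7 of 31 rose, among them CCL5, CXCL10, CCL20 (1.83) and TNFAIP3 (1.80), which encodes the deubiquitinase A20. IFNB1, the gene of interferon beta and the 1 found member of its list, rose by 1.60. Of 13 chemokines found, 3 rose (CCL5, CXCL10 and CCL20), with a list median of 0.08 at percentile 95.2. Among RNA and DNA sensing components, IFIH1, DDX58 (RIG-I, 2.11) and DHX58 (1.87) rose, 3 of 30, with a median of 0.12 at percentile 99.9. These 3 are also counted among the interferon-stimulated genes. The integrated stress and unfolded protein response list had 4 of 34 members that rose, the amino acid transporter subunit SLC3A2 (1.59), ATF3 (1.47), PPP1R15A (1.12) and CHAC1 (1.09), and a median of 0.15 above all random lists. No immediate early gene of 24 met the rule, although the list median of 0.23 was above all random lists; EGR1 stood at 0.75 and ID3 at 0.69. Over all members on the array, without the detection filter that a rise helps to pass, the medians were 0.37 for interferon-stimulated genes, 0.19 for NF-kappaB targets and 0.09 for the stress response list.

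Other lists held no gene meeting the rule in HEK293 except that of IL-4 and STAT6 response genes, where CCL20 was the 1 of 20. Its median was 0.08 at percentile 97.6, and 0.03 without the detection filter. Reference genes had the lowest median, -0.40, below all random lists, with TFRC at -0.51 and PGK1 at -0.50; ribosomal protein genes had -0.24 (percentile 0.04; RPS24 -0.51) and heat shock genes -0.14 (percentile 1.32; HSPA4 -0.32, HSPH1 -0.24). These 3 medians were above 0, at 0.12, 0.06 and 0.06, on the array with poly(I:C) in Cy5 alone. Cholesterol and fatty acid synthesis genes had a median of -0.18 (percentile 0.04; FDFT1 and SQLE both -0.49). Medians of the cell cycle genes (-0.06; CDT1 0.88, E2F8 0.51), p53 targets and apoptosis genes (0.03; GADD45B 0.86, PMAIP1 0.71) and MHC class I genes (-0.04; B2M 0.87, CANX -0.38) lay inside the central 95% of random lists, as did those of leukocyte markers (0.00; CD79A -0.32, ITGAX -0.21) and fibroblast and epithelial markers (-0.01; CDH1 -0.48, MUC1 0.22).

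The second question was the same response in cells that stably express STAT6. OASL rose by 6.54 (92.8-fold), CCL5 by at least 5.92 (at least 60.5-fold), its probe being saturated in the poly(I:C) RNA so that the order of these genes is open, IFIT1 by 5.21, IFIT3 by 5.14 and CCL4L2 by 4.73, a chemokine gene nearly identical to CCL4, so the probe's target is uncertain. ISG15 rose by 4.64, CCL20 by 4.50, ISG20 by 4.27, NFKBIA, the gene of the NF-kappaB inhibitor IkappaB-alpha, by 3.80, and CXCL10 by 3.79. A second CCL5 probe stood at 4.70. The number of genes that rose was 102, and 9 fell: COL2A1 (-1.60), IGFBP5 (-1.38, with a second probe at -0.35), GPC3 (-1.15), NT5DC2 (-1.10), THRA (-1.05), SMOC1 (-1.03, with a second probe at -0.62), CLU (-1.03), PKM2 (-1.03) and TKTL1 (-1.02). Without background correction 5 genes fell, and with a normexp offset of 10 the falls numbered 15. With opposite signs on the arrays, 37 genes had the same sizes. The array with poly(I:C) in Cy5 alone gave 332 genes (282 up, 50 down), the one in Cy3 gave 164 (113 up, 51 down), a threshold of 1.5-fold gave 268 (213 up, 55 down) and one of 3-fold gave 48.

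In this line 25 of 43 interferon-stimulated genes rose, with a median of 1.08, and 13 of 32 NF-kappaB targets, with a median of 0.75; both medians were above all random lists. Without the detection filter they were 0.55 and 0.23, and those of chemokines, sensing components and immediate early genes, given next, were 0.03, 0.10 and 0.34. IFNB1 rose by 3.30 (9.87-fold). Of 15 chemokines 6 rose, including CCL5, CCL20, CXCL10 and IL8 (CXCL8, 2.98), and the median was 0.31 at percentile 99.95, with 0.02 on the array with poly(I:C) in Cy5 alone. The chemokines named here are also counted among the NF-kappaB targets. Sensing components included DHX58 (3.08), DDX58 (2.996), IFIH1 (2.76) and STAT6 itself among 4 of 30 that rose (median 0.25, percentile 99.98). Of these, DHX58, DDX58 and IFIH1 are also counted among the interferon-stimulated genes, and STAT6 is the gene that the line was made to express. Stress response genes that rose were 6 of 35, among them ATF3 (2.53), PPP1R15A (1.99), SLC3A2 (1.67) and DDIT3 (1.26), with a median of 0.23 at percentile 99.99. Immediate early genes, 7 of 24, included EGR1 (2.42), ZFP36 (1.81), JUN (1.21) and FOSB (1.18), with a median of 0.55 above all random lists. B2M (2.02), the light chain of MHC class I, was the 1 of 7 in its list, HSPB8 (1.26) the 1 of 15 heat shock genes, and GADD45B (1.75) and PMAIP1 (1.46) were 2 of 29 p53 targets and apoptosis genes; the medians of these 3 lists, -0.04, 0.09 and 0.01, lay inside the central 95% of random lists.

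Apart from the IL-4 and STAT6 response genes, given further below, no member met the rule in the remaining lists of this line. Cell cycle genes had a median of 0.12 at percentile 98.1 (E2F2 0.94, CDT1 0.90), which was -0.04 on the array with poly(I:C) in Cy3 alone. Ribosomal protein genes had a median of -0.22 at percentile 0.53 (RPL37 -0.61, RPS14 -0.59), with -0.06 on the array with poly(I:C) in Cy5 alone, and cholesterol and fatty acid synthesis genes -0.16 at percentile 0.26 (TM7SF2 -0.61, CH25H 0.60). Reference genes (-0.13; ALAS1 0.70, LDHA -0.48), leukocyte markers (-0.02; CD3D and GNLY both -0.20) and fibroblast and epithelial markers (-0.02; KRT14 0.84, COL5A1 -0.81) had medians inside the central 95%.

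**Figure D1:**
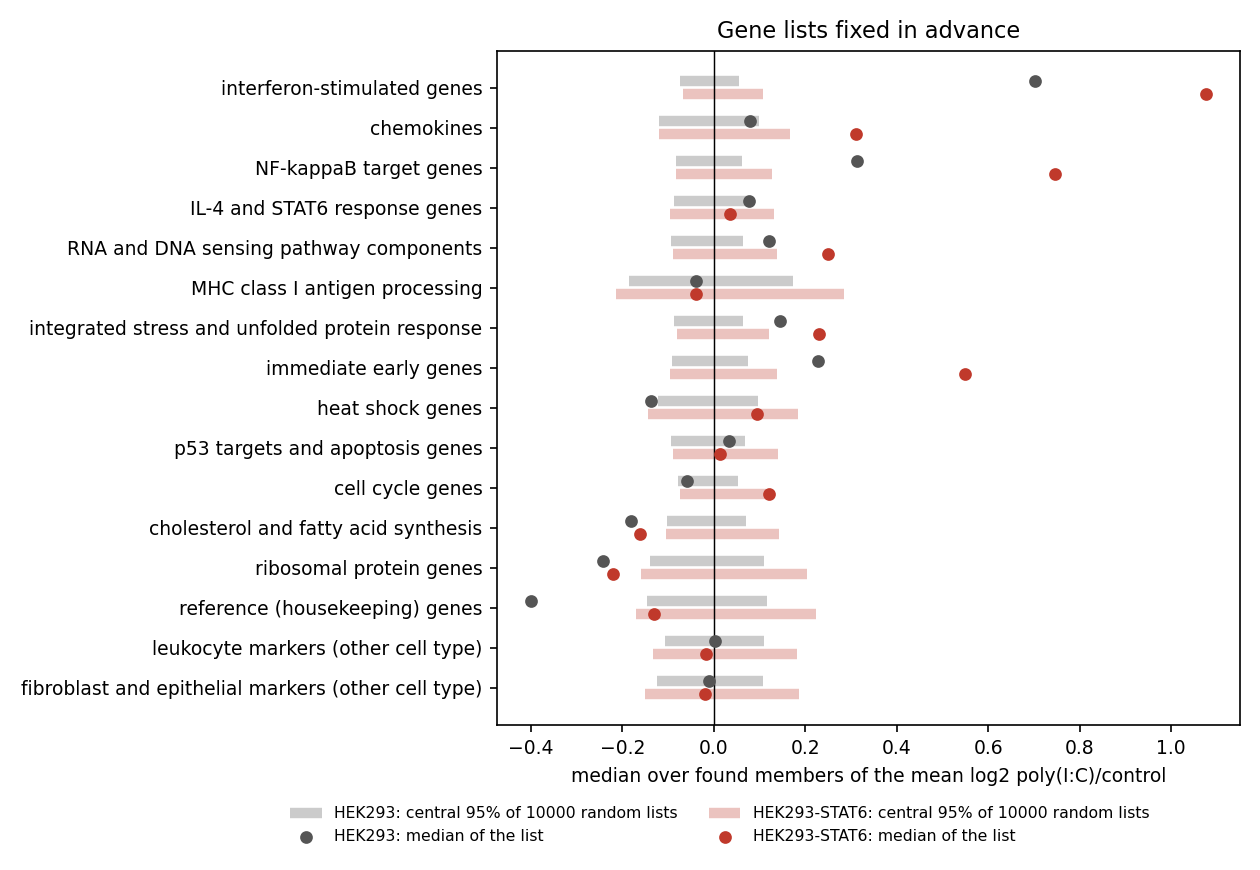
Median over found members of the mean log2 poly(I:C)/control ratio (horizontal axis) for 16 of the 17 gene lists (vertical axis), with the central 95% of 10000 intensity-matched random lists as bars, in HEK293 (grey) and the HEK293-STAT6 line (red). The interferon-stimulated genes lie at 0.70 and 1.08, farthest to the right in both lines.

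The comparison at the centre of the design set the responses of the lines against each other. The response in the HEK293-STAT6 line was higher by a log2 difference of 3.30 for CCL4L2 (4.73 against 1.43), 2.67 for CCL20 (4.50 against 1.83), 2.41 for CCL26, an eotaxin (2.40 against -0.01, where it was not found), 2.26 for NFKBIA (3.80 against 1.54), 2.18 for CCL2 (2.84 against 0.66) and 2.01 for IL8 (2.98 against 0.97). A second CCL2 probe stood at 2.38 against 0.73. OR51B4 (4.18), STAT6 (2.54), MSTP9 (2.45) and C20orf197 (2.05) were the other genes among the 10 largest. The STAT6 probe was saturated after poly(I:C) in the HEK293-STAT6 line and close to the empty spots in HEK293. The size of its difference is therefore uncertain in both directions. By the rule, 38 genes had a higher and 7 a lower response: GNL3L (-1.25), COL2A1 (-1.13), BSG (-1.10), TKTL1 (-1.09), STMN2 (-1.04), PKM2 (-1.02) and C20orf7 (-1.005). For COL2A1 the control level was higher in the HEK293-STAT6 line, as given below, and the difference shares the control RNAs. The technical standard error of a difference was 0.11. The count was 73 with a normexp offset of 10 and 27 with the authors' log2 ratios, 249 at a threshold of 1.5-fold (151 higher, 98 lower) and 14 at 3-fold, and line, culture and array pair cannot be told apart in this design.

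**Figure D2:**
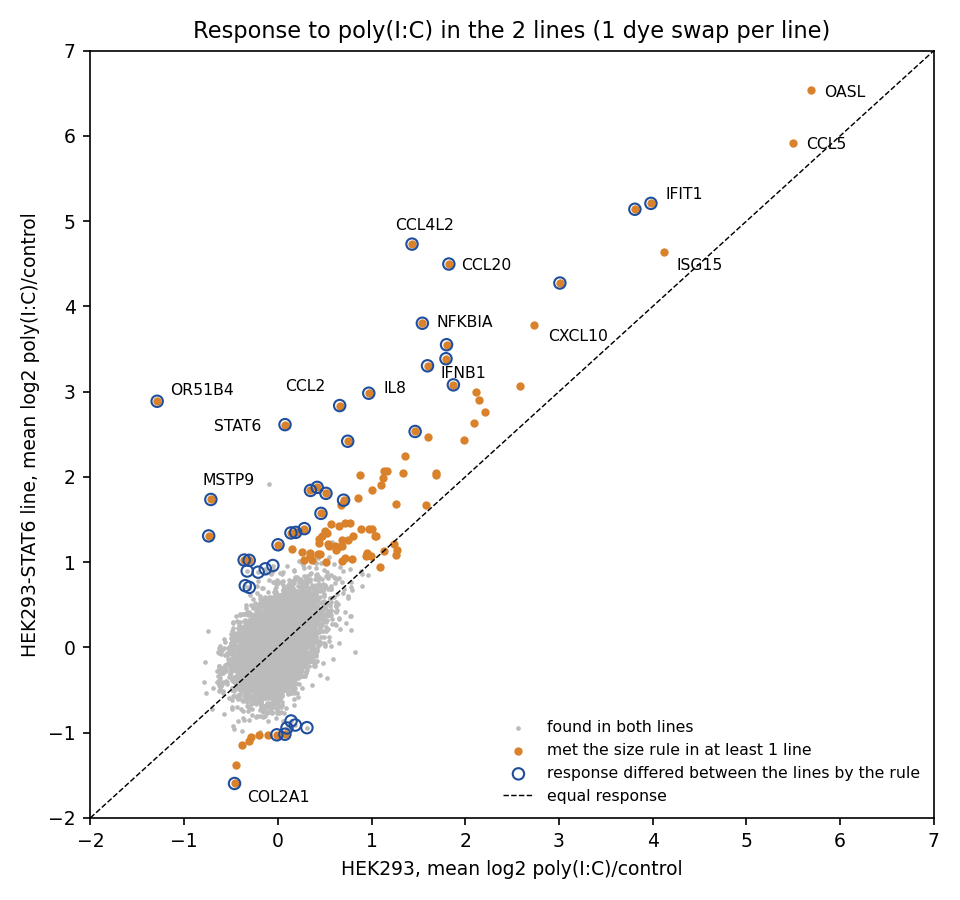
Mean log2 poly(I:C)/control ratio of each of the 9077 genes found in both lines, in HEK293 (horizontal) and the HEK293-STAT6 line (vertical), each the mean of 2 arrays of 1 dye swap. Blue circles mark responses that differed by the rule. Most genes that met the size rule (orange) lie above the dashed line of equal response, among them CCL20 at 1.83 and 4.50; the vertical values of CCL5 (5.92) and STAT6 (2.61) are minimums because of saturation.

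Of the 41 genes that rose in HEK293, 40 also rose in the HEK293-STAT6 line, where independent lists would share 0.438; the exception was CHAC1 (1.09 and 0.95). The response was larger in the HEK293-STAT6 line for 37 of the 41, and 11 of the 40 shared genes met the rule of the difference. Of the 62 genes that rose in the HEK293-STAT6 line and not in HEK293 by the rule, 21 met the rule of the difference, so for the other 41 a difference between the lines was not shown by it. Across the 9077 genes found in both lines, the mean responses correlated with a Pearson r of 0.595 and a Spearman rho of 0.336, genes not being independent replicates. Both orientations of one line correlated at -0.098 in HEK293 and 0.212 in the HEK293-STAT6 line, and the dye terms correlated at 0.887 between the lines. A gene's dye term cancels in its mean, but across genes the means still followed the dye term averaged over the lines. Spearman rho was -0.29 in HEK293 and 0.23 in the HEK293-STAT6 line.

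By list, 7 of 44 interferon-stimulated genes had a higher response in the HEK293-STAT6 line, among them IFIT3 (1.33), ISG20 (1.26), IFIT1 (1.23) and DHX58 (1.21), and the median difference of 0.48 (0.26 without the detection filter) was above all random lists. The same held for 6 of 33 NF-kappaB targets (median 0.35) and for 2 of 25 immediate early genes, EGR1 (1.67) and ZFP36 (1.29; median 0.37), both medians also above all random lists. Higher too were 4 of 16 chemokines, named above (median 0.16, percentile 95.5), IFNB1 (1.71), the sensing components STAT6 and DHX58 (2 of 32; median 0.07), the stress response genes DNAJB11 (1.33) and ATF3 (1.07), 2 of 36 (median 0.05), and HSPB8 (1.37), 1 of 17 heat shock genes (median 0.17). Of the sensing components, DHX58 is also counted among the interferon-stimulated genes, and STAT6 is the gene that the line was made to express. Of the chemokines, CCL20, CCL2 and IL8 are also counted among the NF-kappaB targets. CCL20, CCL26 and CCL2 were put in their lists with knowledge of the study. They add no independent evidence to the counts of chemokines or NF-kappaB targets. For ATF3 the difference rests partly on the control RNA, which stood at -0.73 in the HEK293-STAT6 line against HEK293. Its log2 levels after poly(I:C) were 13.35 and 13.01. Of 22 IL-4 and STAT6 response genes, CCL20, CCL26 and CCL2 were higher, with a list median of 0.10 at percentile 86.7. The study names these 3, so their direction is not independent evidence; none of the other 19 members met the rule, and their median was 0.03. In the HEK293-STAT6 line alone, the same list had 4 of 21 members that rose, CISH (1.15) besides these 3, with a median of 0.04 at percentile 67.0.

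The other lists held no gene whose response differed by the rule. Cell cycle genes had a median difference of 0.17 at percentile 99.7 (PCNA 0.88, CDC2 0.84), and 0.10 with median centring. The difference shares the control RNAs, and the control level of this list was lower in the HEK293-STAT6 line by a like amount (-0.17), as was that of immediate early genes (-0.17) and, more so, of heat shock genes (-0.44). The control level of the single gene B2M stood at -0.60. The medians were 0.21 for reference genes (YWHAZ 0.39, PGK1 0.35), 0.05 for cholesterol and fatty acid synthesis (SC5DL 0.64, MVK -0.58), -0.07 for ribosomal proteins (RPS16 0.36), 0.07 for p53 targets and apoptosis genes (GADD45B 0.89, PMAIP1 0.75), -0.00 for MHC class I genes (B2M 1.15, PDIA3 0.64), -0.06 for leukocyte markers (CD79A 0.27) and -0.01 for fibroblast and epithelial markers (KRT14 0.77, COL5A1 -0.62), all inside the central 95% of random lists.

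The genes fixed in advance are given per array, with poly(I:C) in Cy5 first. In HEK293, STAT6 had log2 ratios of 0.00 and 0.16, and in the HEK293-STAT6 line 2.60 and 2.62; the latter were saturated in the poly(I:C) RNA on both arrays, so STAT6 was at least 6.12-fold higher after poly(I:C). TMEM173, which encodes STING, stood at -0.01 and 0.19 in HEK293 and at -0.30 and 0.10 in the HEK293-STAT6 line. IL29 was not found on both arrays of either line. IFNB1 had 2.001 and 1.19 in HEK293 and 3.36 and 3.25 in the HEK293-STAT6 line. CCL2 had 0.80 and 0.52, then 3.16 and 2.52; CCL20 had 1.82 and 1.83, then 4.31 and 4.68; CCL26 had 0.36 and -0.38, then 2.50 and 2.30. CCL5 had 5.72 and 5.29, then at least 6.08 and 5.76 because of saturation, and ISG15 had 4.12 and 4.12, then 4.50 and 4.79. IFIT1 had 4.49 and 3.47, then 5.37 and 5.05, and IFIT2 had 2.23 and 0.98, then 2.99 and 1.94. CXCL10 had 3.34 and 2.12, then 4.23 and 3.34; it and B2M (1.51 and 0.23, then 2.67 and 1.37) missed the rule of the difference because it compares arrays across dyes, and met a rule within each dye orientation, added after seeing the data, by which 42 genes were higher and 7 lower. IL8 had 1.05 and 0.89, then 3.02 and 2.94, DDX58 had 2.38 and 1.84, then 3.12 and 2.87, TNFAIP3 had 1.80 and 1.80, then 3.50 and 3.60, and IRF1 had 1.84 and 1.55, then 2.03 and 2.05.

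**Figure D3:**
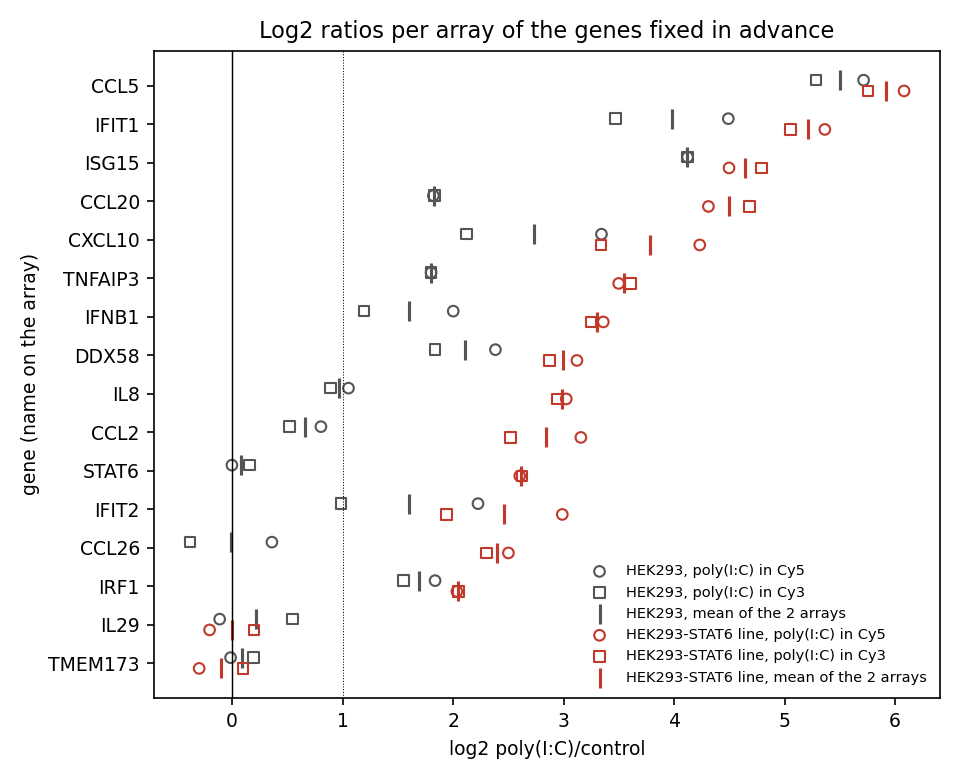
Log2 poly(I:C)/control ratio (horizontal axis) of the 16 genes fixed in advance (vertical axis) on each array, circles for poly(I:C) in Cy5 and squares for poly(I:C) in Cy3, with the mean of both as a tick, in HEK293 (grey) and the HEK293-STAT6 line (red); the dotted line marks a log2 ratio of 1. CCL26 moves from a mean of -0.01 to 2.40, and TMEM173 stays at 0.09 and -0.10.

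The last comparison set the control RNAs of the lines against each other. STAT6 itself was higher in the HEK293-STAT6 control by 6.90 on the log2 scale in Cy5 and 6.23 in Cy3. The mean was 6.57 (94.8-fold), in the direction that the label of the line gives. In HEK293 its probe lay close to the empty spots, so this size is uncertain. Other genes differed far less: CRABP2, a retinoic acid binding protein gene, was higher by 2.45, the cartilage collagen COL2A1 by 2.17, PHLDA2 by 2.11, MDK (midkine) by 2.04, BEX1 by 2.03, PXDN by 2.02, IL32 by 2.01, G0S2 by 1.94 and F10 by 1.82. Lower in the HEK293-STAT6 control were TMEM47 (-4.33), UCHL1 (-3.46), ZWINT (-2.21, with -3.77 in Cy5 and -0.66 in Cy3), SQLE (-1.73), MAOA (-1.72), GK3P (-1.54), NR0B1 (-1.52), DTX3 (-1.50), PDIA3 (-1.47) and CGA (-1.47). TMEM47, MAOA and NR0B1 were not found in the HEK293-STAT6 line and F10 was not found in HEK293, so the sizes and ranks of these 4 are uncertain. In all 87 genes were higher and 87 lower, and 1 gene had the same sizes with opposite signs. The technical standard error was 0.16. The count was 105 without background correction, 287 with an offset of 10, 267 in Cy5 alone, 662 at 1.5-fold (268 higher, 394 lower) and 21 at 3-fold. With the trend across genes on the dye term taken out, an alternative chosen after seeing the data, 85 genes were higher and 39 lower.

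Fibroblast and epithelial markers had a median control level difference of 0.41 at percentile 99.99 (0.15 without the detection filter), with ELF3 (1.53) and COL5A1 (1.31) higher, 2 of 12; leukocyte markers had -0.13 (CD14 -0.27, MS4A1 -0.21). Heat shock genes had the lowest median, -0.44 at percentile 0.01 (HSPA4 -0.73, HSPD1 -0.72), with none of 17 meeting the rule and -0.24 in Cy5 alone, and cell cycle genes had -0.17 at percentile 0.50, with CCND2 (-1.35) and TTK (-1.06) lower, 2 of 51. Immediate early genes had -0.17 at percentile 1.88, with DUSP1 (-1.22) lower. Chemokines had 0.15 at percentile 97.7, and 0.05 without the detection filter (CCL5 0.93, CXCL16 0.89). The remaining medians lay inside the central 95% of random lists, with single members meeting the rule: BST2 (1.22), IL32, STAT6, MYD88 (1.13), FDXR (1.16) and CDKN1A (1.07) were higher, and MAOA, PDIA3, SQLE, IDI1 (-1.23), YWHAZ (-1.16) and TFRC (-1.03) were lower. These belonged to the interferon-stimulated genes (median 0.06), NF-kappaB targets (0.04), sensing components (0.11), p53 targets and apoptosis genes (0.08), IL-4 and STAT6 response genes (0.06), MHC class I genes (0.04), cholesterol and fatty acid synthesis (-0.14) and reference genes (-0.11). Among stress response genes (median 0.04) GDF15 stood at 0.91 and HERPUD1 at -0.84, among ribosomal proteins (-0.14) RPL37 at 0.89 and RPL15 at -0.79, and IFNB1 at -0.01.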

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

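Of the tests in this part, the one of a common factor, those on OR51B4, MSTP9 and C20orf197 and the one on fibroblast genes were chosen after the values had been seen; the 2 tests on the trend with the dye term were set down before their results. For OR51B4, MSTP9 and C20orf197 a test on the genes together gave 0.35 and left the question open, and the test was then taken gene by gene, and for C20orf197 also apart for the dye and for single spots; the one on fibroblast genes was first written for fibroblasts or epithelial cells and narrowed after its value was seen. The alternative that takes out this trend was itself added after seeing the data.

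In 7 named genes the log2 ratios had opposite signs in the lines on all 4 arrays, and the difference was at least 1; with 1 RNA per condition it was not tested. OR51B4 differed by 4.18 (-1.56 and -1.02 in HEK293, 2.41 and 3.36 in the HEK293-STAT6 line), MSTP9 by 2.45, C20orf197 by 2.05 (their control levels in the HEK293-STAT6 line, RNAs that the difference shares, stood at -1.34, -0.78 and -0.49 against HEK293), HSPB8 by 1.37, DNAJB11 by 1.33, GNL3L by -1.25 and C20orf7 by -1.005. For HSPB8 (not found in HEK293), DNAJB11, GNL3L, C20orf7 and C20orf197, at least 1 HEK293 array lay within 0.53 of 0. That is 3 technical standard errors of a single array for dim probes. The error of brighter probes is smaller, and the bound was not fitted to the intensity of each gene. By this bound, a response of HEK293 in the opposite direction is not shown for these 5. Probes without a gene name stand outside the comparisons of genes: 8 of 5106 found in HEK293 and 34 of 5089 found in the HEK293-STAT6 line rose by the same rule.

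OR51B4 fell in HEK293, where MSTP9 (-0.71) and C20orf197 (-0.74) did not meet the rule, and all 3 rose in the HEK293-STAT6 line. An exchange of the control and poly(I:C) RNA in one line would have turned all genes, yet 40 of the 41 genes that rose in HEK293 rose in the other line too. For OR51B4 and MSTP9 the smallest log2 ratios in the direction of the line were 1.02 and 0.70. Both lay beyond 3 technical standard errors of a single array for dim probes (0.53). OR51B4 met the size rule in both lines, which asks for at least 0.58 on each array. Its outcome was therefore fixed beforehand and tests nothing. MSTP9 met that rule only in the HEK293-STAT6 line, so only its HEK293 arrays were free to differ. There its direction did not rest on 1 array. For C20orf197 the smaller mean of both orientations was 0.74 in size against 0.37, but its smallest single ratio was 0.35, so a spot defect stays open. These genes had been picked because the signs agreed within each line and both arrays of one line lay beyond both of the other. A dye effect that turns sign with the orientation could hardly have entered, so these values are no independent test of it. Among 14484 probes found on all arrays, 4, of which 2 have no name, were lower in HEK293 and higher in the HEK293-STAT6 line with every array beyond 0.4, and 0 showed the reverse. A high level in the single HEK293 control RNA, a probe reading another transcript, and a true difference between the lines or cultures, stay open and were not tested.

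The larger responses of the HEK293-STAT6 line were weighed next. If a larger share of cells responded, or one factor raised every gene, the fold excess would be multiplied by the same number throughout; the median factor was 2.10, and 25 of 39 genes that rose in both lines without saturation lay over 3 technical standard errors from the difference it predicts. That error leaves out variation between cultures, so with 1 culture per condition this cannot decide, and one factor stays open. A trend across genes with the dye term ran through the difference (Spearman rho 0.459), but with it taken out 32 of the 38 genes with a higher response still met the rule, so it is not the whole cause. An unequal strength of stimulation per cell, a property of the clone, and STAT6 itself may each contribute and cannot be separated with 1 culture per condition.

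The control levels of the lines differed along the same trend, with a Spearman rho of -0.417 between the dye term and the control level difference, against -0.090 for the poly(I:C) level difference. Taking the trend out left 101 of the 174 genes, 68 of the 87 higher and 33 of the 87 lower ones, so a technical gradient may account for part of the list, mainly among lower genes, and not for all of it. Fibroblasts mixed into the HEK293-STAT6 culture would bring their abundant transcripts, but 0 of 5 (COL1A1, COL1A2, COL3A1, DCN and LUM) met the rule, with COL1A1 at 0.50 and COL1A2 at 0.13, and COL3A1 and DCN not found in either line. Epithelial cells stay open and were not tested: the list of fibroblast and epithelial markers had a median of 0.41 at percentile 99.99, with the epithelial genes ELF3 at 1.53, CDH1 at 0.75, TACSTD1 at 0.62, MUC1 at 0.61, KRT14 at 0.25 and CLDN4 at 0.07, and the fibroblast gene COL5A1 at 1.31. Differences that arose when the stable line was derived stay open and were not tested.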

How the results depend on the processing

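The alternatives were fixed before the data were examined, except the removal of the trend on the dye term and the comparison of the lines within each dye orientation. Of the genes called in HEK293 (42), the HEK293-STAT6 line (111), the difference (45) and the control level (174), none was called in the opposite direction under any alternative run. On the array with poly(I:C) in Cy5 alone the counts were 91 in HEK293 and 332 in the HEK293-STAT6 line (282 rose, 50 fell), and with poly(I:C) in Cy3 alone 216 in HEK293 (60 rose, 156 fell), since a single orientation keeps the dye term; Cy5 alone gave 267 genes for the control level. At 1.5-fold the counts were 73, 268, 249 and 662, and at 3-fold 22, 48, 14 and 21, in the order above. A normexp offset of 10 gave 73 for the difference and 287 for the control level; no background correction gave 105 for the control level; and the authors' log2 ratios gave 27 for the difference, 26 of them among the 45. The authors' ratios need a probe found in both lines. They also followed loess without background correction, a setting that by itself gave 34 for the difference. What made up the rest was not tested. The other alternatives kept each total within 1.5 times, but not each direction: with poly(I:C) in Cy3 alone 113 genes rose and 51 fell in the HEK293-STAT6 line, and lower responses numbered 16 in Cy5 alone, 13 in Cy3 alone and 3 without background correction, against 7. Falls in the HEK293-STAT6 line numbered 5 without background correction and 15 with an offset of 10, against 9. Lower control levels numbered 132 in Cy3 alone, against 87. With the trend taken out the counts were 44, 105, 38 and 124 (85 higher and 39 lower for the control level). Within each dye orientation the difference counted 49 genes, with all 45 among them. The correlation of the responses (0.595) was 0.616 without background correction, 0.574 with an offset of 10, 0.614 with the authors' ratios, 0.499 without a detection filter, 0.757 with poly(I:C) in Cy5 alone and 0.714 in Cy3 alone. Of the list medians that lay outside the central 95% of random lists, 4 changed sign: with poly(I:C) in Cy5 alone, in HEK293, heat shock genes at 0.0584, ribosomal protein genes at 0.0551 and reference genes at 0.1246, and with poly(I:C) in Cy3 alone, in the HEK293-STAT6 line, cell cycle genes at -0.0370; a single orientation again keeps the dye term. Over all list medians and alternatives, 498 values moved by less than the technical standard error of a single gene. It was 0.07 for a line, 0.11 for the difference and 0.16 for the control level. Another 74 moved by more without such a change of sign. That error is not the error of a list median, and many list medians are smaller than it. These counts therefore do not measure how stable the medians are. For named genes 1266 values moved by less than it and 583 by more, and none that met the rule changed sign. Signal over background limits dim genes, whose folds are understated. The response and the difference have no replicate within a line; a paired test of poly(I:C) over both lines was not run.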

Other observations

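Some genes rose in both lines by almost the same amount. The fold minus 1 in the HEK293-STAT6 line, divided by that in HEK293, was 1.09 for SLC3A2, 0.97 for ETV4, 0.81 for RASSF1 and 0.86 for the small nucleolar RNA gene SNORA24, against 15.1 for CCL4L2, 8.49 for CCL20, 6.77 for NFKBIA and 4.38 for IFNB1. These genes were chosen after their values were seen. The 16 interferon-stimulated genes that rose in both lines lay between 1.38 and 2.80.

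STAT6 rose in the line that stably expresses it, by at least 6.12-fold, while HEK293 had a mean log2 ratio of 0.08 at intensities of 135 to 233, against 95th percentiles of empty spots from 104 to 195, so a response there was hardly measurable. The STAT6 level in the HEK293-STAT6 line was therefore not the same before and after poly(I:C). Which copy of the gene gave the rise was not tested.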
